A study of Mus musculus with 28 samples.

How the data were processed

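RNA sequencing was carried out on total RNA from whole liver of 28 mice on a BGI DNBSEQ instrument, per the labels. The authors deposited, for each sex, a table of whole-number read counts per gene and a table of CPM values, which are counts scaled to the library total, both with 1 column per animal and 32544 genes. The deposited CPM values were checked against the deposited counts and equal each count over its library total with no further scaling, within a tolerance of 1e-04 CPM for 100% of values (largest difference 4.99e-06 in males and 4.44e-05 in females). Per the submitters' processing notes, FastQC and edgeR were used and the genome was GRCm38 (mm10), and the notes as used here give no versions and no roles. The aligner, the counting program, the gene annotation and whether counting used strand are not given in the sources used here. If reads that match several genes were discarded or shared out, counts of near-identical genes are uncertain, which applies to the major urinary protein genes, the Cyp3a41a, Cyp3a44 and Cyp3a16 group, Gsta1 with Gm10639, Gstp1 with Gstp2, and the Serpina1 family. All 56 columns were used.

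Animals were grouped by the sex, genotype and diet in the labels. Each label carries its own animal number, so no animals were paired. Libraries held between 18741939 and 22652285 counts. Intervals below cover the spread between animals or counting error, and reads carry no molecular identifiers, so counting error is a lower limit of technical error.

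Values computed here start from the deposited counts. Library totals were scaled with TMM factors in edgeR 4.0.16 (R 4.3.3), and genes were kept by filterByExpr on the groups, which left 14078 genes in males, 13999 in females and 14685 in the fit of both sexes. CPM values printed in the results are TMM-normalised and so differ from the deposited CPM by the library's factor. They are means with the SD over the animals of a group. Each sex was fitted with a mean per group and a robust quasi-likelihood dispersion shared by the groups of that sex, so that small groups borrow spread from the others. Contrasts were tested with edgeR's quasi-likelihood F test, p-values were adjusted by Benjamini-Hochberg over all tested genes in a contrast, and adjusted p under 0.05 was called. The biological coefficient of variation was 0.161 in males and 0.199 in females. The contrasts were KO against CT on each diet, HFC against CTD in each genotype, their interaction, the mean KO effect over both sexes, and sex differences as female minus male. Log2 fold changes carry a standard error (SE) computed as their size over the square root of the F statistic. It is an approximation, not an error estimated by the fit, and may be too small for genes with few counts. The confidence intervals of Myc use the same value.

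The 36 gene lists cover liver cell types, metabolic pathways, inflammation, matrix, cell cycle, Myc targets and sex-biased genes. They hold 683 genes, 7 of them in more than 1 list, and of 693 list entries 2 are not in the tables. The exocrine pancreas and adipose tissue lists had too few tested members, and the other 34 were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. The same test with an estimated correlation was an alternative. Genes of a list are not independent, and camera with the preset value called many lists in random splits of the animals, so lists reported as called by camera are given with both p-values. Exact two-sided permutation tests of each animal's mean list score were added after the data were seen. In males 4 animals against 4 allow 70 regroupings, and in females 3 against 3 allow no p below 0.1.

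Genes were named by a fixed rule. Myc came first. Then came the 5 largest rises and the 5 largest falls among called genes with a mean of at least 5 CPM in a compared group and replicate values that did not overlap, and then, list by list in order of camera p, up to 4 called members by adjusted p, or up to 2 members with the smallest p where none was called, given as values. Not every gene that this rule selects is reported here. Genes outside this rule are said to have been chosen after their values were seen. Gene symbols were used as the tables give them, and 96.5% match GENCODE M21 names on GRCm38, from which coordinates were taken, counted from 1.

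The steps were tested on simulated counts before any contrast of the deposited counts was tested. Gene means, dispersions and library sizes for the simulation came from a fit of the deposited counts. For KO against CT on HFC in males (14078 genes), 48% of 50 genes changed by log2 0.5 were recovered, 86% at 1, 94% at 1.5 and 98% at 2, with 1 false call among 13713 unchanged genes. For the same comparison in females (13999 genes) the shares were 4%, 64%, 86% and 90%, with 6 false calls. A collagen list moved by log2 0.5 was called by camera in both sexes, with 0 of 33 other lists called, and also with an estimated correlation (adjusted p = 1.76e-05 in males and 0.00346 in females). The simulated genes vary independently, unlike those of a real list. Changed genes were drawn only from those above a floor of expected counts. Apart from the set changes all groups shared the same means and dispersions, so neither a diet effect nor an animal standing apart was simulated.

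Alternatives planned before the data were examined were DESeq2 size factors, no count filter, a mean of at least 1 CPM, the DESeq2 1.42.0 Wald test, limma-trend on log2 of the deposited CPM plus 1, the compared groups fitted alone, a term for the animal-number series within HFC, an estimated correlation for lists, and leaving out each animal in turn. Library totals without TMM factors, and lists limited to members tested in both sexes, were added after the data were seen.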

Results

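RNA was sequenced from whole livers of 28 C57BL/6 mice, 1 library per animal, at 13 weeks of age by the labels. Control mice carrying floxed alleles (CT) were compared with mice in which c-Myc, a transcription factor that drives growth and proliferation genes, was deleted from endothelial cells after tamoxifen (KO). Tamoxifen was given at 5 weeks of age, and 2 weeks later the mice went onto either a low-fat control diet (CTD) or a diet high in fat and cholesterol (HFC) for 5 weeks. These steps add to 12 weeks, 1 less than the age given. The series concerns the part played by endothelial c-Myc in diet-induced inflammation and fibrosis of the liver. The combination of sex, genotype and diet gave 8 groups, with 4 males or 3 females in each. Total counts were 22154774 to 22652285 per male library and 18741939 to 19195502 per female library. Between 17096 and 18036 genes had at least 1 count in a library. Counts of the Y-linked gene Ddx3y were 1323 to 1763 in the male libraries and 0 to 6 in the female ones, as the sex labels imply. Animals of the same group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of at least 12.7 in the 24 male pairs and 21 in the 12 female pairs. The animal numbers of the CTD and HFC mice lie in separate ranges, so a cohort difference and the diet cannot be told apart.

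The make-up of the libraries differed with diet. The 115 most abundant genes of males held 50.8 ± 1.91% of counts in CT males on CTD and 46.5 ± 1.59% in CT males on HFC (SD, n = 4). The major urinary protein genes, a family of 21 secreted carriers made by hepatocytes, held 7.05 ± 2.77% of counts in CT males on CTD and 2.36 ± 1.18% on HFC. In CT females the same family held 1.94 ± 0.474% on CTD and 0.227 ± 0.162% on HFC (SD, n = 3). Mitochondrial transcripts made up 11.9 ± 0.655% of counts in CT males on CTD and 10.7 ± 0.535% on HFC. TMM factors, which scale out such shifts, were 0.842 to 0.999 on CTD and 1 to 1.19 on HFC. With library totals in place of TMM factors the median diet effect over all tested genes moved from -0.01 to 0.22 log2 in CT males, from -0.02 to 0.26 in KO males, from 0.00 to 0.30 in CT females and from 0.02 to 0.32 in KO females. Changes below are relative to the TMM scale.

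Myc itself (chromosome 15, 61985391 to 61990374, GRCm38) was measured in every liver before anything else. Male CT livers on CTD held 6.09, 4.73, 7.8 and 7.05 CPM of Myc, and male KO livers on CTD held 20.1, 6.88, 14.9 and 3.09 CPM. On HFC the male CT livers held 6.29, 3.58, 11.3 and 12.4 CPM and the male KO livers 20, 8.9, 5.62 and 11.2 CPM. Female CT livers held 5.44, 12 and 4.6 CPM on CTD and 9.71, 5.46 and 4.38 CPM on HFC. Female KO livers held 7.26, 20.5 and 7.81 CPM on CTD and 12.1, 4.65 and 13.3 CPM on HFC. The KO to CT ratio of Myc was 1.36 in males on HFC (95% confidence interval 0.611 to 3.04, edgeR adjusted p = 0.96) and 1.75 in males on CTD (0.763 to 4.02, adjusted p = 0.842). In females it was 1.54 on HFC (0.653 to 3.61, adjusted p = 1) and 1.62 on CTD (0.685 to 3.82, adjusted p = 0.999). Endothelial cells are a minor part of liver RNA and other liver cells express Myc, so the whole-liver level does not check the endothelial deletion.

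**Figure D1:**
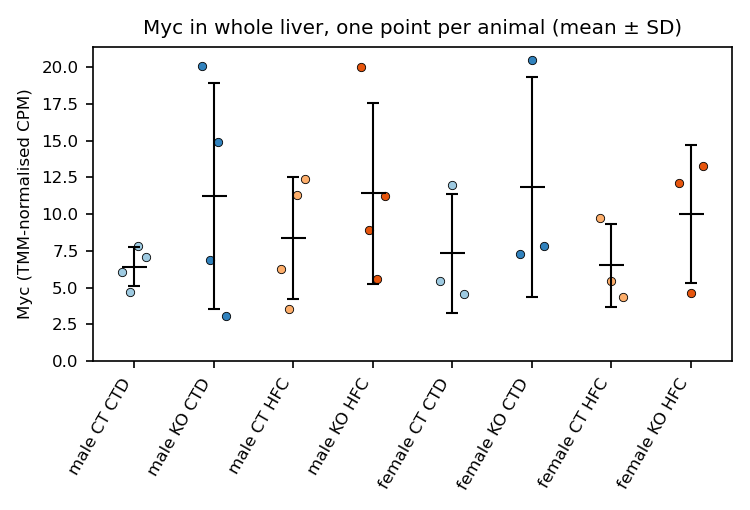
Myc in TMM-normalised CPM (vertical axis) for each of the 8 groups (horizontal axis), 1 point per animal, with the group mean and SD. KO and CT points overlap in each sex and diet, with values from 3.09 to 20.5 CPM.

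Which genes the HFC diet changed in control males was addressed first, and 2820 of 14078 tested genes passed, 1497 higher and 1323 lower on HFC. Cyp8b1 (chromosome 9, 121914356 to 121916305), the enzyme that makes cholic acid, went from 140 ± 22.7 to 1.07 ± 1.53 CPM (SD, n = 4, log2 fold change -7.01, SE 0.68, adjusted p = 6.62e-05), with 3.36 CPM in CT HFC 543 and at most 0.442 CPM in the other HFC animals. Genes of macrophages and antigen presentation rose. H2-Ab1 (chromosome 17, 34257689 to 34269419), an MHC class II chain, went from 19.4 ± 4.9 to 119 ± 44 CPM (log2 2.62, SE 0.24, adjusted p = 2.86e-05). Among genes of at least 5 CPM in a group and with no overlap between animals, the largest rises were those of the glutathione transferases Gsta1 (log2 6.53, SE 1.34), its near-identical neighbour Gm10639 (6.16) and Gstm3 (5.22, SE 1.26), of the steroid hydroxylase Cyp2a4 (4.79, SE 1.14) and of the aldo-keto reductase Akr1b7 (4.62). Male CT HFC 418 carried much of their size, and without it Gsta1 was at log2 4.76, Gm10639 at 4.42, Gstm3 at 3.59 and Akr1b7 at 3.53, all still called. By the same rule the largest falls besides Cyp8b1 were in the urinary protein genes Mup7 (log2 -7.38, SE 1.67), Mup12, Mup15 and Mup17, whose near-identical copies make counts of single members uncertain. Mup7 was at 6.67 and 2.67 CPM in CT HFC 416 and 418 and at 100 and 170 CPM in 417 and 543, so the mean on HFC rests on the latter 2 animals. The call of Mup15 was lost without CT HFC 416, 417 or 418, at adjusted p = 0.0513, 0.0553 and 0.0511.

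Gene lists, written before the deposited values were opened, showed in CT males which kinds of gene moved together. Of 21 macrophage and monocyte markers 19 rose (19 adjusted over the list alone), among them Cd52 (log2 1.73, SE 0.22) and Aif1 (1.23, SE 0.17), and 0 fell. The list as a whole was called by camera (adjusted p = 1.27e-14), with adjusted p = 0.191 with an estimated correlation. Of 10 genes of MHC class II presentation 9 rose (10 adjusted over the list alone; camera adjusted p = 6.83e-11, adjusted p = 0.137 with an estimated correlation), with H2-Eb1 at log2 2.78 (SE 0.28). Of 18 markers of recruited and lipid-associated macrophages 11 rose and 1 fell (13 and 1 adjusted over the list alone), including the hyaluronan receptor Cd44 (1.42, SE 0.16), the chemokine receptor Ccr2 (1.65, SE 0.25) and the lipid sensor Trem2 (1.62, SE 0.24). That list had camera adjusted p = 4.17e-08 and adjusted p = 0.191 with an estimated correlation. Of 27 chemokines and cytokines 12 rose (14 adjusted over the list alone; camera adjusted p = 8.61e-08, adjusted p = 0.137 with an estimated correlation), with Cxcl9 at 1.73 (SE 0.26), Ccl8 at 3.46 (SE 0.63) and Tnf at 2.72 (SE 0.47). Of 22 T and NK cell markers 12 rose (13 adjusted over the list alone), such as Cd8a (1.14, SE 0.21). The T and NK list had camera adjusted p = 1.8e-07, and adjusted p = 0.137 with an estimated correlation. Of 16 targets of NRF2, the regulator of the oxidative stress response, 14 rose and 1 fell, and Gstm1 rose by log2 2.62 (SE 0.37) and Ephx1 by 1.71 (SE 0.24). The NRF2 list had camera adjusted p = 1.97e-08 and adjusted p = 0.191 with an estimated correlation.

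Lipid metabolism lists moved in both directions in CT males. Of 25 genes of cholesterol synthesis and uptake 15 fell (17 adjusted over the list alone) and 0 rose, including the sterol enzymes Nsdhl (log2 -1.82, SE 0.24), Tm7sf2 (-1.26, SE 0.16) and Hsd17b7 (-0.81, SE 0.10). The camera test of the list gave adjusted p = 3.69e-11, and adjusted p = 0.192 with an estimated correlation. Of 23 genes of fatty acid and triglyceride synthesis 12 fell and 1 rose (14 and 1 adjusted over the list alone), with Thrsp at -1.91 (SE 0.27) and Acss2 at -1.33 (SE 0.21). By camera, the list had adjusted p = 1.54e-05, and adjusted p = 0.209 with an estimated correlation. Of 12 sterol efflux and LXR target genes 5 rose, among them the cholesterol transporters Abcg1 (1.63, SE 0.16) and Abcg5 (1.25, SE 0.18) and the lipase Lpl (2.07, SE 0.37). This list had camera adjusted p = 0.00781, and adjusted p = 0.137 with an estimated correlation. Of 20 genes of bile acid synthesis and transport 6 rose and 9 fell, with the exporter subunit Slc51b at 2.97 (SE 0.35) and the uptake transporter Slc10a1 at -1.17 (SE 0.18), and the list was not called (adjusted p = 0.327). Hepatocyte identity genes also fell in part, 6 of 19 (8 adjusted over the list alone). Camera gave the list adjusted p = 5.57e-05, and adjusted p = 0.209 with an estimated correlation. Of 40 collagen and matrix genes 2 rose, Tgfb1 (0.75, SE 0.18) and Col5a3 (0.42, SE 0.09), and 38 did not pass. The matrix list had camera adjusted p = 0.00528 and adjusted p = 0.678 with an estimated correlation, and its call was lost without CT CTD 313 (median log2 0.16, adjusted p = 0.11). Of 20 stellate cell markers 0 passed (median log2 0.05). The count of all called genes was 1753 without CT HFC 418. With library totals it was 4537, of which 4127 were higher and 410 lower, and with limma on the deposited CPM it was 4614, 4194 higher and 420 lower. On library totals the medians of the bile acid (-0.17 to 0.06), fatty acid oxidation (-0.12 to 0.11) and endothelial (-0.04 to 0.18) lists changed sign.

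**Figure D2:**
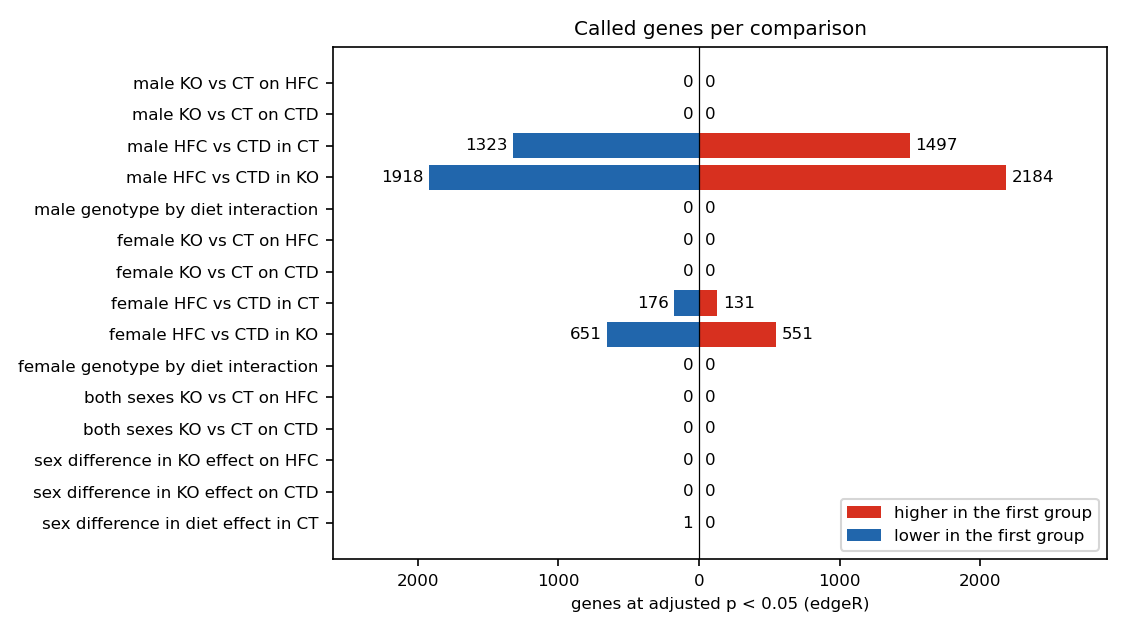
Number of genes at adjusted p under 0.05 by edgeR (horizontal axis) in each of the 15 comparisons (vertical axis), with higher genes to the right and lower genes to the left, where a sex difference is female minus male. The diet comparisons reach 4102 genes in KO males, and the KO against CT comparisons are at 0.

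In KO males the same diet comparison gave 4102 called genes of 14078, 2184 higher and 1918 lower on HFC. Cyp8b1 went from 151 ± 26.8 to 1.12 ± 1.06 CPM (SD, n = 4, log2 -7.09, SE 0.68, adjusted p = 1.01e-05) and H2-Ab1 from 15.3 ± 1.82 to 166 ± 28.7 CPM (log2 3.44, SE 0.25, adjusted p = 6.34e-07). By the rule used in CT males the largest rises included Acod1, which makes itaconate in activated macrophages, from 0.108 ± 0.0875 to 6.4 ± 1.89 CPM (log2 5.80, SE 0.61), the lysosomal glycoprotein Gpnmb (5.70, SE 1.42) and the ubiquitin-like Ubd (5.07, SE 0.59). All 21 macrophage and monocyte markers rose (camera adjusted p = 2.84e-20, adjusted p = 0.0864 with an estimated correlation), with Adgre1, which encodes F4/80, at log2 1.66 (SE 0.16). All 10 MHC class II genes rose. As a whole, the list had camera adjusted p = 6.72e-12, and adjusted p = 0.0864 with an estimated correlation. Of 10 Kupffer cell markers 9 rose, with Timd4 at 1.77 (SE 0.16) and Clec1b at 1.21 (SE 0.13). The Kupffer list had camera adjusted p = 6.47e-09, and adjusted p = 0.109 with an estimated correlation. Of 22 T and NK markers 18 rose (19 adjusted over the list alone), including Cd3e (2.70, SE 0.41). The camera test of the list gave adjusted p = 2.23e-11, and adjusted p = 0.0864 with an estimated correlation. Of 28 cell cycle genes 19 rose and 1 fell (20 and 1 adjusted over the list alone), with Top2a at 1.80 (SE 0.27) and Plk1 at 2.54 (SE 0.44). By camera, the list had adjusted p = 4.1e-06, and adjusted p = 0.281 with an estimated correlation.

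The diet also raised matrix genes in KO males. Of 40 collagen and matrix genes 16 rose and 1 fell (20 and 2 adjusted over the list alone), with Tgfb1 at log2 1.24 (SE 0.18), Postn at 0.96 (SE 0.19) and Fbn1 at 1.35 (SE 0.29). This list had camera adjusted p = 8.5e-05, and adjusted p = 0.457 with an estimated correlation. Its median of 0.77 was 0.35 without KO HFC 414 (adjusted p = 0.0034). Of 25 fatty acid oxidation genes 13 fell and 1 rose (15 and 1 adjusted over the list alone), among them Cpt1a (-0.66, SE 0.09). Camera gave the list adjusted p = 6.28e-05, and adjusted p = 0.281 with an estimated correlation. Of 25 cholesterol genes 16 fell (19 adjusted over the list alone), with Tm7sf2 at -1.60 (SE 0.16) and Nsdhl at -1.70 (SE 0.23). As a whole, the list had camera adjusted p = 4.06e-09, and adjusted p = 0.218 with an estimated correlation. Of 16 NRF2 targets 14 rose and 1 fell, with Hmox1 at 1.46 (SE 0.20) and Nqo1 at 1.74 (SE 0.26). The NRF2 list had camera adjusted p = 1.38e-06, and adjusted p = 0.193 with an estimated correlation. The sterol transporter Abcg1 (chromosome 17, 31057675 to 31117988) rose from 6.68 ± 1.01 to 32 ± 6.33 CPM (log2 2.26, SE 0.16, adjusted p = 2.36e-07). Of 30 endothelial markers 3 rose, Cdh5 (0.84, SE 0.14) among them, and the list was not called (camera adjusted p = 0.116). In exact two-sided permutation tests of each animal's mean list score, 24 of 34 lists passed in KO males (smallest adjusted p = 0.0405) and 0 in CT males (smallest adjusted p = 0.0572). In CT males 17 lists were at unadjusted p under 0.05. These and the 24 lists of KO males were all at the smallest value that 70 regroupings allow, 0.0286. Passing after adjustment then depends only on how many lists reach that value, so 24 against 0 does not measure a difference between the genotypes. With library totals the split of called genes in KO males was 5585 higher and 511 lower.

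Whether the diet effect differed by genotype in males was tested as an interaction, and 0 of 14078 genes passed with edgeR, with 852 genes at unadjusted p under 0.05 and 0 calls by limma. Diet effects in CT and KO males correlated across genes (Pearson 0.83, Spearman 0.77, genes not being independent replicates), and the 2229 genes called in both genotypes all had the same sign, 1223 up and 1006 down, where independent lists would share 232 and 180. DESeq2 called 5 genes, named here after their values were seen: the Kupffer cell lectin gene Clec1b (log2 0.94, DESeq2 adjusted p = 0.00511), Kcna2, Treml4 and the predicted genes Gm10359 and Gm12671. By lists, the diet rise of macrophage and monocyte markers was larger in KO males by a median log2 of 0.75, with 19 of 21 markers passing when adjusted over the list alone and 0 when adjusted over all genes. The camera test of the list gave adjusted p = 1.9e-18, and adjusted p = 0.192 with an estimated correlation. Mpeg1 (0.91, SE 0.27) and Ctss (0.88, SE 0.26) were examples that did not pass over all genes. Kupffer cell markers had a median of 0.69 (7 of 10 adjusted over the list alone; camera adjusted p = 2.57e-09, adjusted p = 0.192 with an estimated correlation), and MHC class II genes 0.88 (6 of 10 adjusted over the list alone). The MHC class II list had camera adjusted p = 1.57e-07, and adjusted p = 0.232 with an estimated correlation. T and NK markers had a median of 0.56 (camera adjusted p = 4.95e-07, adjusted p = 0.192 with an estimated correlation; 0.34 without KO CTD 304) and B and plasma cell markers one of 0.61 (camera adjusted p = 3.21e-05, adjusted p = 0.192 with an estimated correlation). Fatty acid oxidation genes had a median of -0.22. This list had camera adjusted p = 2.55e-08, and adjusted p = 0.232 with an estimated correlation. In exact two-sided permutation tests of list scores, 8 of 34 lists were at unadjusted p under 0.05, with the smallest, 0.00571, for T and NK markers, and 0 after adjustment (smallest adjusted p = 0.116). Of the 30 endothelial markers 0 passed, with a median of 0.14.

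**Figure D3:**
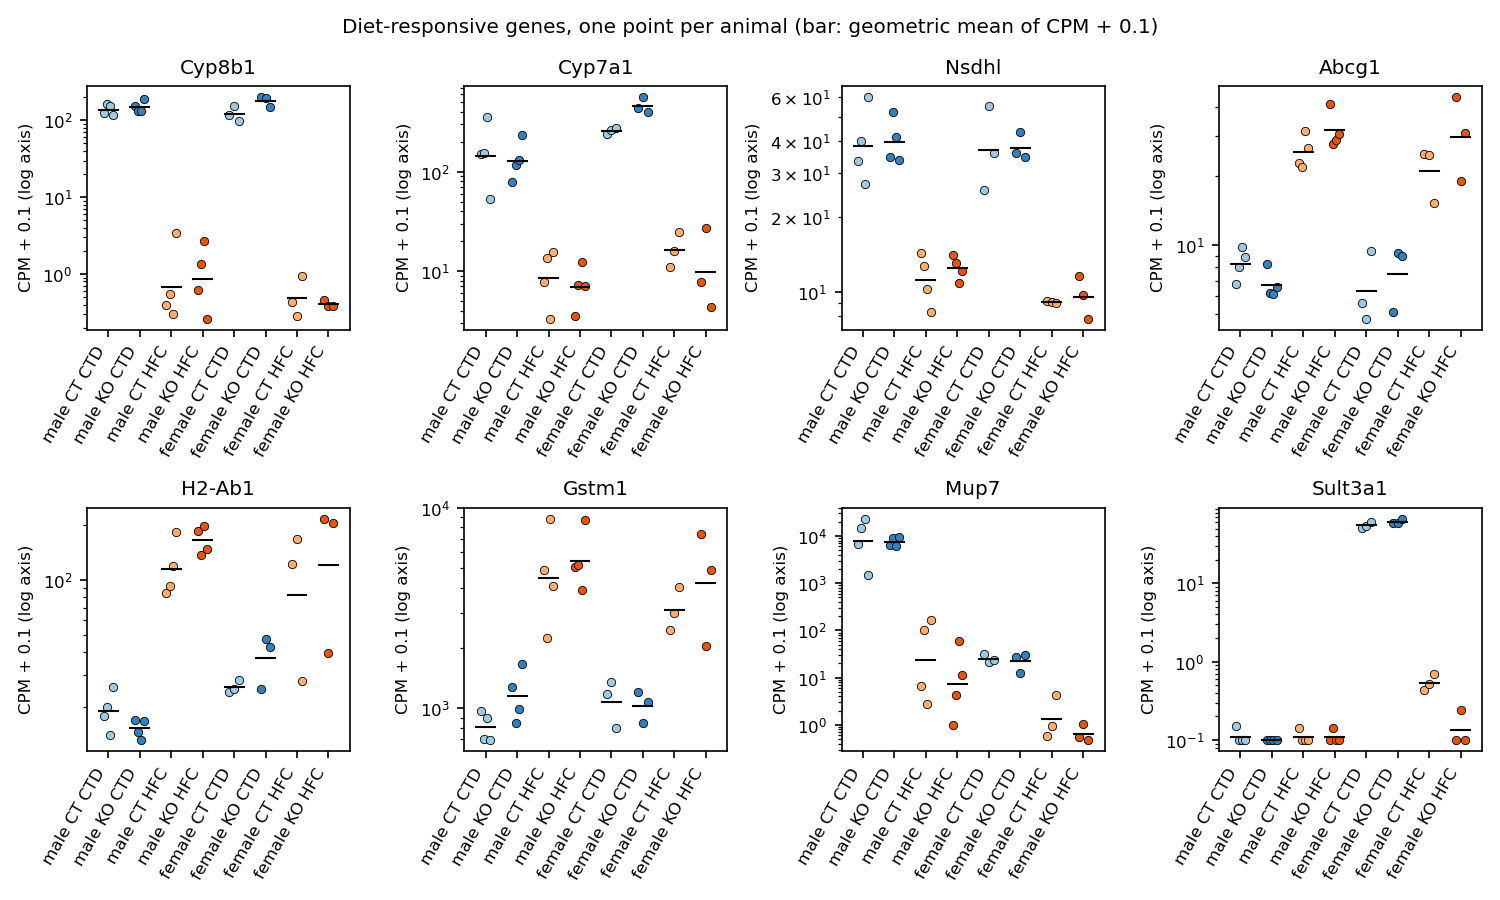
CPM plus 0.1 on a log axis (vertical) for diet-responsive genes in each group (horizontal), 1 point per animal, with a bar at the geometric mean. Cyp8b1 was at 118 to 165 CPM in CT males on CTD and at 0.2 to 3.36 CPM on HFC, before 0.1 is added.

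Control females were then compared between diets, and 307 of 13999 tested genes passed, 131 higher and 176 lower on HFC. Among the largest falls were those of female-predominant liver genes. Cyp3a41a (chromosome 5, 145694049 to 145720136), a P450 with near-identical copies, went from 1610 ± 398 to 2.91 ± 2.58 CPM (SD, n = 3, log2 -9.12, SE 0.65, adjusted p = 9.97e-05). The sulfotransferase gene Sult3a1 (chromosome 10, 33857721 to 33879532) went from 55.3 ± 4.97 to 0.445 ± 0.131 CPM (log2 -6.95, SE 0.26, adjusted p = 1.3e-08), and Cyp8b1 from 122 ± 28.2 to 0.456 ± 0.352 CPM (log2 -8.09, SE 0.35, adjusted p = 5.34e-08). Rises with no overlap between animals included the progenitor marker Prom1 (1.15 ± 0.318 to 10.4 ± 2.64 CPM), Adam11 (log2 2.42, SE 0.28), the cell cycle inhibitor Cdkn1a (2.51, SE 0.54), Lpl (2.61, SE 0.42) and Gpnmb (4.59, SE 0.96). The call of Lpl was lost without CT CTD 306, CT CTD 308, CT HFC 420 or CT HFC 510, at adjusted p = 0.0732, 0.0611, 0.0593 and 0.0594. The calls of Gpnmb and Cdkn1a were lost without any 1 of the 6 animals, at adjusted p from 0.0515 to 0.189 for Gpnmb and from 0.0615 to 0.189 for Cdkn1a.

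Among the lists in CT females, cholesterol genes again fell, 11 of 25 (21 adjusted over the list alone) and 0 rose, with Idi1 at log2 -2.52 (SE 0.34), Nsdhl at -2.11 (SE 0.24), Cyp51 at -2.01 (SE 0.23) and Tm7sf2 at -1.79 (SE 0.23). Camera gave the list adjusted p = 4.09e-17, and adjusted p = 0.365 with an estimated correlation. Of 16 female-biased liver genes 4 fell (6 down and 1 up adjusted over the list alone). As a whole, the list had camera adjusted p = 5.62e-07, and adjusted p = 0.365 with an estimated correlation. The epoxide hydrolase Ephx1, an NRF2 target, rose from 135 ± 18.4 to 561 ± 11.6 CPM (log2 2.05, SE 0.21, adjusted p = 0.000636) and was the 1 of 16 list members to pass (4 adjusted over the list alone). The NRF2 list had camera adjusted p = 0.000141, and adjusted p = 0.374 with an estimated correlation. Of 21 macrophage and monocyte markers 0 passed, also when adjusted over the list alone, with a median log2 of 0.78. The camera test of the list gave adjusted p = 1.64e-05, and adjusted p = 0.425 with an estimated correlation, and the median was 0.51 without CT CTD 306 and 1.52 without CT CTD 318. Of 10 MHC class II genes 0 passed (8 adjusted over the list alone; median 1.88, camera adjusted p = 0.00061, adjusted p = 0.374 with an estimated correlation). H2-Ab1 was at 24 to 28 CPM in CT females on CTD and at 121, 166 and 27.6 CPM on HFC, the last in CT HFC 512. All 30 endothelial markers had positive values and 0 passed (7 adjusted over the list alone), with a median of 0.49. By camera, the list had adjusted p = 3.7e-09, and adjusted p = 0.374 with an estimated correlation. Hepatocyte identity genes had a median of -0.34, and 1 of 19 fell. This list had camera adjusted p = 6.53e-05, and adjusted p = 0.374 with an estimated correlation. Abcg5 rose by log2 0.96 (SE 0.15) and the glutathione-degrading stress gene Chac1 by 1.41 (SE 0.22). The count of 307 was 85 without CT CTD 306, 118 without CT CTD 308, 72 without CT HFC 420 and 72 without CT HFC 510. It was 919 by DESeq2, 804 with these groups fitted alone, 1798 by limma on the deposited CPM (1647 higher, 151 lower) and 1832 with library totals (1687 higher, 145 lower). On library totals the medians of the fatty acid synthesis (-0.24 to 0.04) and oxidation (-0.17 to 0.12) lists changed sign.

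In KO females 1202 of 13999 genes passed, 551 higher and 651 lower on HFC. Cyp8b1 went from 182 ± 28.6 to 0.311 ± 0.0472 CPM (SD, n = 3, log2 -9.16, SE 0.37, adjusted p = 1.99e-08) and Cyp7a1 (chromosome 4, 6265612 to 6275633), the rate-limiting enzyme of bile acid synthesis, from 464 ± 86.5 to 13 ± 12.4 CPM (log2 -5.16, SE 0.64, adjusted p = 0.00165). On HFC Cyp7a1 was at 27.1 CPM in KO HFC 413 and at 7.63 and 4.24 CPM in 412 and 419. Sult3a1 went from 61.5 ± 4.71 to 0.0474 ± 0.0821 CPM, a level at the limit of counting. Gpnmb (chromosome 6, 49036546 to 49070929) rose by log2 5.94 (SE 0.92, adjusted p = 0.00497) and Trem2 from 4.32 ± 1.65 to 17.3 ± 7.39 CPM (log2 2.00, SE 0.31, adjusted p = 0.00255). Of 25 cholesterol genes 19 fell (22 adjusted over the list alone; camera adjusted p = 8.25e-17, adjusted p = 0.278 with an estimated correlation), Idi1 (-2.41, SE 0.34) and Nsdhl (-1.98, SE 0.24) among them. Of 16 NRF2 targets 10 rose (12 adjusted over the list alone; camera adjusted p = 2.38e-08, adjusted p = 0.278 with an estimated correlation), such as Gclc (1.60, SE 0.21) and Gstm1 (2.21, SE 0.39). Of 16 female-biased genes 7 fell and 1 rose. Camera gave the list adjusted p = 6.7e-09, and adjusted p = 0.278 with an estimated correlation. Of 19 hepatocyte identity genes 9 fell (13 adjusted over the list alone), including Tat (-1.88, SE 0.31) and Ass1 (-1.47, SE 0.25). As a whole, the list had camera adjusted p = 6.57e-08, and adjusted p = 0.278 with an estimated correlation. Of 18 recruited macrophage markers 8 rose (14 adjusted over the list alone), including Lpl (3.37, SE 0.43) and Cd9 (1.40, SE 0.21). The recruited macrophage list had camera adjusted p = 4.54e-07, and adjusted p = 0.42 with an estimated correlation. Of 18 clock genes 5 fell, with Ciart at -2.18 (SE 0.34). The camera test of the list gave adjusted p = 0.000337, and adjusted p = 0.326 with an estimated correlation. Of 40 matrix genes 2 rose (4 up and 1 down adjusted over the list alone), Col5a3 at 1.87 (SE 0.25) and Mmp12 at 3.42 (SE 0.64). By camera, the list had adjusted p = 0.00104, and adjusted p = 0.527 with an estimated correlation. The call of Mmp12 was lost without KO CTD 309 (adjusted p = 0.0508) and with these groups fitted alone (adjusted p = 0.0621), and that of the matrix list without KO CTD 307 (median 0.29, adjusted p = 0.085).

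The count in KO females moved with each library. It was 565 without KO CTD 307, 585 without KO CTD 309, 630 without KO CTD 317, 665 without KO HFC 412, 765 without KO HFC 419 and 2671 without KO HFC 413. It was 1884 by DESeq2, 435 with these groups fitted alone, 3485 by limma on the deposited CPM (3070 higher, 415 lower) and 3738 with library totals (3358 higher, 380 lower). On library totals the median of the fatty acid oxidation list moved from -0.29 to 0.02. Of 10 MHC class II genes 0 passed in KO females (6 adjusted over the list alone; median 1.78, camera adjusted p = 0.00148, adjusted p = 0.491 with an estimated correlation), and H2-Ab1 was at 39.6 CPM in KO HFC 413, within the 24.9 to 47.4 CPM of CTD, against 216 and 204 CPM in the others. Across genes the CT and KO diet effects in females had a Pearson correlation of 0.78 and a Spearman correlation of 0.65, and the 255 genes called in both had the same sign, 106 up and 149 down, where independent lists would share 5.16 and 8.18. The interaction of genotype and diet in females called 0 genes with edgeR (546 at unadjusted p under 0.05, 0 by DESeq2 and 0 by limma). Without KO HFC 413 it called 1, the leucine-rich repeat gene Lrrc3 (log2 -1.17, adjusted p = 0.0451), named after its values were seen. NRF2 targets had a median interaction of 0.70 in females. This list had camera adjusted p = 0.00142, and adjusted p = 0.961 with an estimated correlation, and the median was 0.32 without KO HFC 412.

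**Figure D4:**
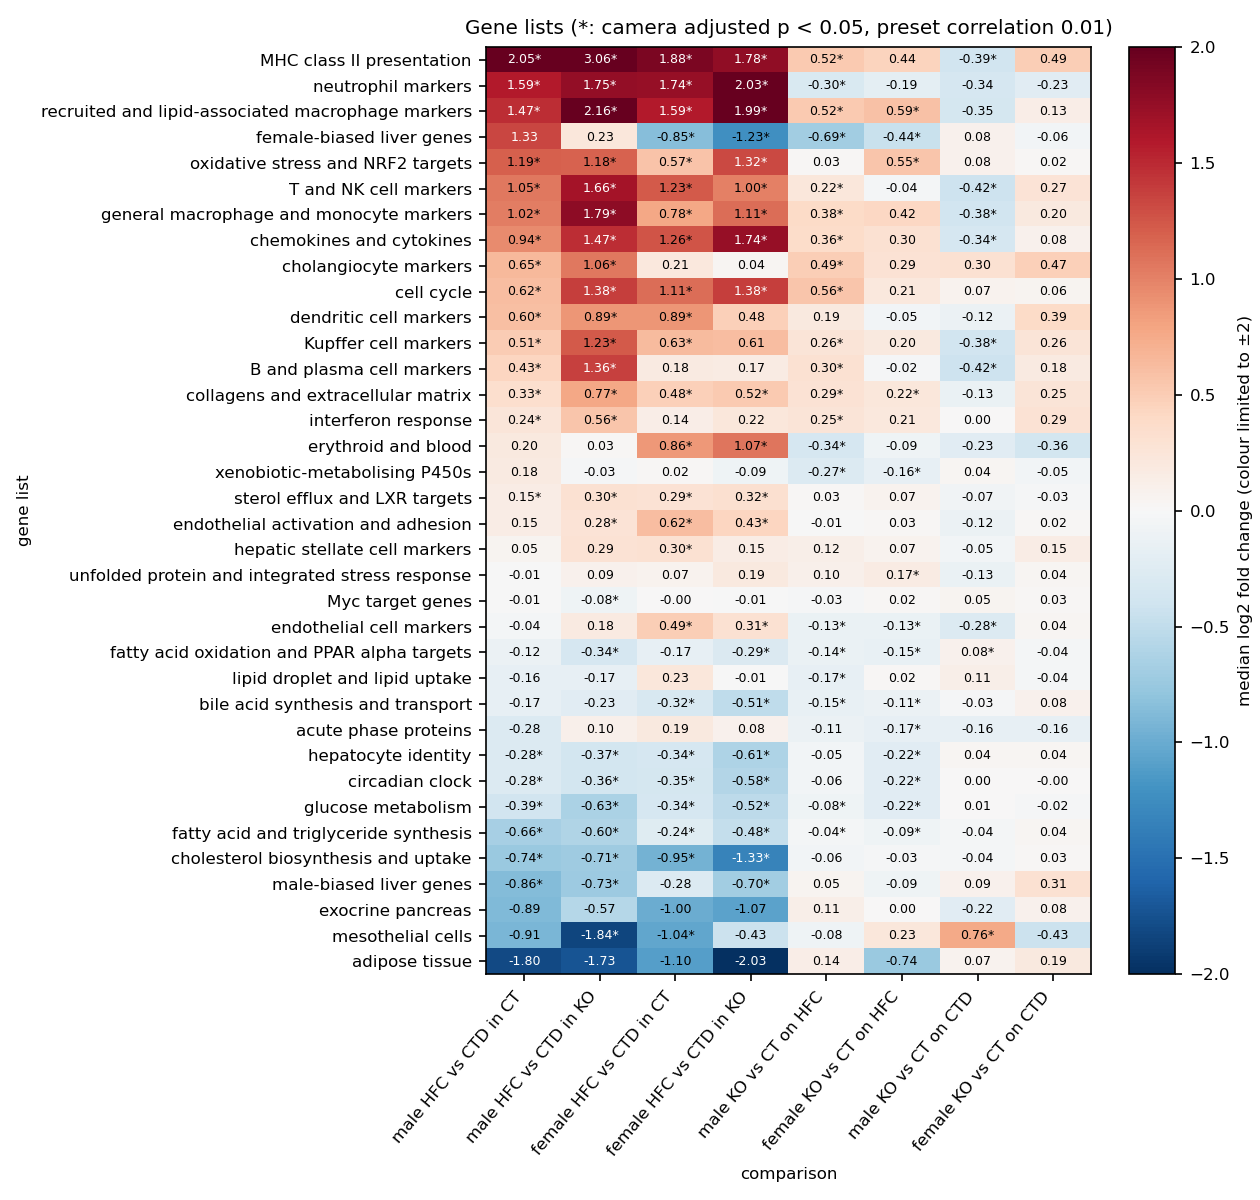
Median log2 fold change of each gene list (vertical axis) in 8 comparisons (horizontal axis), with colour limited to a log2 of 2 in either direction and an asterisk at camera adjusted p under 0.05 with the preset correlation. With an estimated correlation 0 lists pass in these comparisons. The macrophage list is at 1.02 and 1.79 for the diet in CT and KO males, and the cholesterol list at -0.74 and -0.71.

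Whether the diet effect in control livers differed between the sexes was tested as female minus male over 14685 genes, and 1 gene passed with edgeR (1013 at unadjusted p under 0.05). Car2 (chromosome 3, 14886273 to 14900770), a carbonic anhydrase, went from 18.2 ± 1.12 to 8.75 ± 0.912 CPM in CT females (SD, n = 3) and from 5.51 ± 0.6 to 6.33 ± 0.54 CPM in CT males (SD, n = 4), a difference of log2 -1.30 (SE 0.18, adjusted p = 0.00127). DESeq2 called 44 genes and limma 24. The edgeR count was 2 without male CT HFC 418, 4 without female CT CTD 308, 12 without female CT CTD 318, 2 without female CT HFC 420 and 3 without female CT HFC 512. Female-biased liver genes differed most among the lists, with a median of -2.32 and 8 of 16 lower when adjusted over the list alone (camera adjusted p = 1.21e-21, adjusted p = 0.00788 with an estimated correlation). Of the 16 members 7 had too few counts to be tested in males, so that their difference restates the female fall. Over the 9 tested in each sex the median was -1.45 (camera adjusted p = 0.000289, adjusted p = 0.905 with an estimated correlation), and of these 2 rose and 1 fell on HFC in CT males. Cyp2b13, a female-predominant P450, was at 0.147 CPM in CT males on CTD and 4.99 ± 6.45 CPM on HFC (log2 4.94, SE 1.22, adjusted p = 0.0124), a call that was lost with these groups fitted alone (adjusted p = 0.0647), and at 194 ± 43.4 and 153 ± 87.4 CPM in CT females. Male CT HFC 416 carried much of the male mean, with 345 counts against 20, 93 and 22 in 417, 418 and 543. The 30 endothelial markers were all positive in the difference (median 0.47, camera adjusted p = 2.54e-13, adjusted p = 0.578 with an estimated correlation), with a median of 0.31 without female CT CTD 306. Of 13 male-biased genes 4 fell on HFC in CT males. Camera gave the list adjusted p = 0.00493, and adjusted p = 0.464 with an estimated correlation. Diet effects in CT males and females correlated across genes (Pearson 0.73, Spearman 0.63), and the 204 genes called in both had the same sign. In KO livers the correlation was 0.75 and 822 of 826 genes called in both sexes had the same sign.

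The main question of the series, KO against CT on HFC, was asked in males with 4 livers a side. No gene passed with edgeR, 0 of 14078, with 653 at unadjusted p under 0.05, 3 by DESeq2 and 0 by limma. The 653 genes are 4.64% of those tested, where a share of 0.05 is expected with no effect. Across the contrasts of the KO effect, with interactions and sex differences, this share was 1.35 to 6.74%. The 3 genes called by DESeq2, named after their values were seen, were the predicted genes Gm10359, Gm12671 and Gm12918, whose fitted changes are too large to be read as folds. By camera with the preset correlation macrophage, cell cycle and matrix lists lay above the other genes, but 0 of 34 lists passed with an estimated correlation and 0 were at unadjusted p under 0.05 in exact two-sided permutation tests of list scores. Neutrophil markers lay below the other genes (median log2 -0.30, camera adjusted p = 0.0111, adjusted p = 0.438 with an estimated correlation). The neutrophil call was lost without CT HFC 418 (-0.14, adjusted p = 0.078) or KO HFC 414 (-0.22, adjusted p = 0.089) and with genes of at least 1 CPM alone (-0.23, adjusted p = 0.24). Macrophage and monocyte markers were positive in 21 of 21 cases with a median log2 of 0.38 and 0 passing (camera adjusted p = 2.71e-10, adjusted p = 0.346 with an estimated correlation), and Aif1 was at 5.24 ± 0.942 CPM in CT and 7.26 ± 1.63 CPM in KO livers (SD, n = 4, log2 0.47, SE 0.16, adjusted p = 0.958). Cell cycle genes were positive in 28 of 28 cases with a median of 0.56 (camera adjusted p = 5.53e-10, adjusted p = 0.346 with an estimated correlation), and the mitotic checkpoint kinase gene Bub1b was at 1.13 ± 0.19 and 2.24 ± 0.82 CPM. Interferon response genes had a median of 0.25 (camera adjusted p = 1.71e-07, adjusted p = 0.346 with an estimated correlation), with the nucleic acid sensor Zbp1 at 15.8 ± 2.76 and 22.4 ± 3.82 CPM. MHC class II genes had a median of 0.52 in 10 of 10 positive cases (camera adjusted p = 4.99e-07, adjusted p = 0.346 with an estimated correlation), with H2-DMb1 at log2 0.56 (SE 0.20). Chemokines and cytokines had a median of 0.36 (1 passing adjusted over the list alone; camera adjusted p = 5.04e-05, adjusted p = 0.346 with an estimated correlation), with Il1b at log2 0.90 (SE 0.24). Without KO HFC 414 the medians of macrophage, cell cycle and chemokine genes were 0.25, 0.30 and 0.18, and without CT HFC 416 that of interferon response genes was 0.15.

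Fatty acid oxidation genes lay lower in KO males on HFC, with a median of -0.14 (camera adjusted p = 3.28e-07, adjusted p = 0.346 with an estimated correlation), and the lipase inhibitor Angptl4 was at 130 ± 16.1 CPM in CT and 88.9 ± 21.1 CPM in KO livers (log2 -0.55, SE 0.14). Of 40 collagen and matrix genes 34 were positive, with a median of 0.29 (camera adjusted p = 0.00297, adjusted p = 0.625 with an estimated correlation), and Fbn1 was at log2 0.50 (SE 0.28). The matrix call was lost without CT HFC 416 (median 0.22, adjusted p = 0.089) or CT HFC 417 (0.24, adjusted p = 0.059), and without KO HFC 414 the median was -0.04 (adjusted p = 0.46). Recruited macrophage markers had a median of 0.52 (camera adjusted p = 0.000361, adjusted p = 0.421 with an estimated correlation), which was 0.08 without KO HFC 414 (adjusted p = 0.26). Endothelial markers had a median of -0.13 (camera adjusted p = 0.00668, adjusted p = 0.625 with an estimated correlation), which was 0.01 without CT HFC 416 (adjusted p = 0.78) and -0.10 without KO HFC 539 (adjusted p = 0.2). Stellate cell markers (median 0.12, adjusted p = 0.0548) and Myc targets (median -0.03, adjusted p = 0.14) were not called.

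Female KO and CT livers on HFC differed in 0 of 13999 genes with edgeR, with 311 at unadjusted p under 0.05, 0 by DESeq2 and 0 by limma. These KO females are numbered 412, 413 and 419 and the CT females 420, 510 and 512, so genotype and animal-number series are partly confounded. With a term for the series the genotype comparison rests on CT HFC 420 as the only control. That fit therefore cannot tell genotype from series, and the lists were not tested with that term. NRF2 targets lay above the other genes with a median log2 of 0.55, and 4 of 16 were higher when adjusted over the list alone. As a whole, the list had camera adjusted p = 8.3e-08, and adjusted p = 0.658 with an estimated correlation, and its median was 0.33 without KO HFC 412. Cell cycle genes, called in males only with the preset correlation, were not called in females (median 0.21, camera adjusted p = 0.921), which is no test of a sex difference. The carbonyl reductase Cbr3 was at 1.11 ± 0.517 CPM in CT and 6.27 ± 6.26 CPM in KO livers (SD, n = 3, log2 2.48, SE 0.74), and Ugdh, which makes UDP-glucuronate, at 71.9 ± 4.73 and 124 ± 50.2 CPM. Female-biased liver genes had a median of -0.44. The female-biased list had camera adjusted p = 1.44e-06, and adjusted p = 0.658 with an estimated correlation, and its median was -0.14 without KO HFC 412 and -0.87 without KO HFC 419. Recruited macrophage markers had a median of 0.59 (camera adjusted p = 0.000205, adjusted p = 0.713 with an estimated correlation), which was 0.03 without KO HFC 412 (adjusted p = 0.95), and Trem2 was at 8.94 ± 1.09 and 17.3 ± 7.39 CPM. Endothelial markers had a median of -0.13 (camera adjusted p = 9e-04, adjusted p = 0.713 with an estimated correlation), and the VEGF receptor Flt1 was at log2 -0.41 (SE 0.19). Of 40 matrix genes 34 were positive with a median of 0.22 (camera adjusted p = 0.00645, adjusted p = 0.753 with an estimated correlation), a call lost without CT HFC 510 (0.14, adjusted p = 0.068), KO HFC 412 (0.09, adjusted p = 0.95) or KO HFC 413 (0.19, adjusted p = 0.15). On HFC, H2-Ab1 stayed within the range of CTD females in KO HFC 413 (39.6 CPM) and in CT HFC 512 (27.6 CPM). Leaving out 413 alone thus takes such an animal from the KO side only. Without KO HFC 413, edgeR called 9 genes, named after their values were seen. Ugdh (log2 1.09, adjusted p = 0.00916), Cbr3 (adjusted p = 0.0157), Gstp1 (1.04, adjusted p = 0.0371), Gstp2 (1.70, adjusted p = 0.0157) and Srxn1 (1.34, adjusted p = 0.0331) were higher in KO livers. Sult3a1 (adjusted p = 0.0211, with 0 counts in the remaining KO livers, so that no fold is given), Cyp2c50 (log2 -1.33, adjusted p = 0.0227), Cyp4f14 (-1.37, adjusted p = 0.0157) and Lrrc3 (-0.84, adjusted p = 0.0157) were lower.

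With both sexes in one fit, KO against CT on HFC gave 0 of 14685 genes with edgeR, 906 at unadjusted p under 0.05, 2 by DESeq2 and 0 by limma. Chac1 (log2 -0.88, DESeq2 adjusted p = 0.0189) and Gm12918 were the genes DESeq2 called, and without female KO HFC 413 edgeR called Rras (0.48, adjusted p = 0.0193), all named after their values were seen. Fatty acid oxidation genes had a median of -0.14 (camera adjusted p = 3.35e-07, adjusted p = 0.509 with an estimated correlation), NRF2 targets 0.31 (camera adjusted p = 3.66e-05, adjusted p = 0.509 with an estimated correlation) and endothelial markers -0.15. The endothelial list had camera adjusted p = 0.000158, and adjusted p = 0.526 with an estimated correlation. Without female KO HFC 412 the fatty acid oxidation and NRF2 medians were -0.08 and 0.19, and without male CT HFC 416 the endothelial median was -0.07. Collagen and matrix genes were positive in 35 of 40 cases with a median of 0.26 (camera adjusted p = 0.000674, adjusted p = 0.533 with an estimated correlation), a call lost without male KO HFC 414 (0.09, adjusted p = 0.17) or female KO HFC 412 (0.22, adjusted p = 0.059). Macrophage markers had a median of 0.40 (camera adjusted p = 0.000205, adjusted p = 0.526 with an estimated correlation), which was 0.20 without female KO HFC 412 (adjusted p = 0.17). In permutation tests of list scores over both sexes on HFC 0 of 34 lists passed after adjustment, and the 1 list at unadjusted p under 0.05 was sterol efflux and LXR targets (0.09, p = 0.00429, adjusted p = 0.146). Unadjusted p was 0.109 for fatty acid oxidation, 0.181 for NRF2, 0.11 for endothelial, 0.274 for matrix and 0.313 for macrophage genes. The sex difference of the KO effect on HFC called 0 genes with edgeR (198 at unadjusted p under 0.05, 1 by DESeq2, which was Gm12918, and 0 by limma).

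On the control diet, macrophage and endothelial marker lists were lower in male KO than CT livers by camera with the preset correlation, but 0 lists passed with an estimated correlation. Permutation of the scores gave unadjusted p = 0.0571 for macrophage and 0.171 for endothelial markers. With edgeR 0 of 14078 genes passed, with 949 at unadjusted p under 0.05, 11 by DESeq2 and 0 by limma. Macrophage and monocyte markers were negative in 21 of 21 cases with a median log2 of -0.38 (camera adjusted p = 6.45e-10, adjusted p = 0.734 with an estimated correlation), and Csf1r, the receptor for colony-stimulating factor, was at 70.5 ± 15.4 CPM in CT and 49.9 ± 5.39 CPM in KO livers (SD, n = 4, log2 -0.50, SE 0.15). Kupffer cell markers had a median of -0.38, with 7 of 10 lower when adjusted over the list alone (camera adjusted p = 3.36e-07, adjusted p = 0.573 with an estimated correlation), and Clec1b was at 14 ± 2.57 and 8.79 ± 0.752 CPM. Endothelial markers were negative in 29 of 30 cases with a median of -0.28 (camera adjusted p = 1.14e-08, adjusted p = 0.792 with an estimated correlation), with Pecam1, or CD31, at 17.7 ± 1.76 and 13.1 ± 2.69 CPM and the scavenger receptor Stab2 at 59.6 ± 5.6 and 44 ± 8.58 CPM. T and NK markers had a median of -0.42 (camera adjusted p = 0.000444, adjusted p = 0.573 with an estimated correlation), and Cd3e was at log2 -1.70 (SE 0.45). That call was lost without CT CTD 320, where the macrophage median was -0.24 (T and NK median -0.46, adjusted p = 0.079) and with genes of at least 1 CPM alone (median -0.20, adjusted p = 0.12). DESeq2 called Clec1b (log2 -0.67, DESeq2 adjusted p = 0.00845), the mannose receptor Mrc1 (-0.62, DESeq2 adjusted p = 0.0148) and the pan-leukocyte gene Ptprc (-0.72, DESeq2 adjusted p = 0.0418) among its 11, chosen here after their values were seen. Its 11 calls also held genes that were higher in KO livers. These were Zbtb7c (log2 2.22, DESeq2 adjusted p = 0.000627), Csad (0.99), Setd4 (0.92) and 1810026J23Rik (0.31). In exact two-sided permutation tests of list scores 1 of 34 lists was at unadjusted p under 0.05, the T and NK list (p = 0.0286, adjusted p = 0.646).

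Female KO and CT livers on CTD differed in 0 of 13999 genes with edgeR, with 446 at unadjusted p under 0.05, 0 by limma and 1 by DESeq2, the centriole gene Fbf1 (log2 -1.07, DESeq2 adjusted p = 0.0436), named after its values were seen. No list was called by camera (smallest adjusted p = 0.144), while 10 lists were called as higher without KO CTD 307, 8 without CT CTD 318 and 2 without CT CTD 308. Over both sexes 0 of 14685 genes passed with edgeR, with 741 at unadjusted p under 0.05, 0 by limma and 1 by DESeq2, the RNA helicase gene Dhx37. Dhx37 also passed with edgeR without female CT CTD 308 (log2 0.55, adjusted p = 0.0276). The sex difference of the KO effect on CTD, female minus male, called 0 genes with edgeR (813 at unadjusted p under 0.05, 0 by DESeq2 and 0 by limma). Macrophage markers had a median difference of 0.60 (camera adjusted p = 1.75e-05) and endothelial markers one of 0.28 (camera adjusted p = 1.75e-05), both with adjusted p = 0.99 with an estimated correlation. The macrophage value was 0.28 without female CT CTD 306 and 1.23 without female CT CTD 318, and the endothelial one 0.16 without female CT CTD 306.

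**Figure D5:**
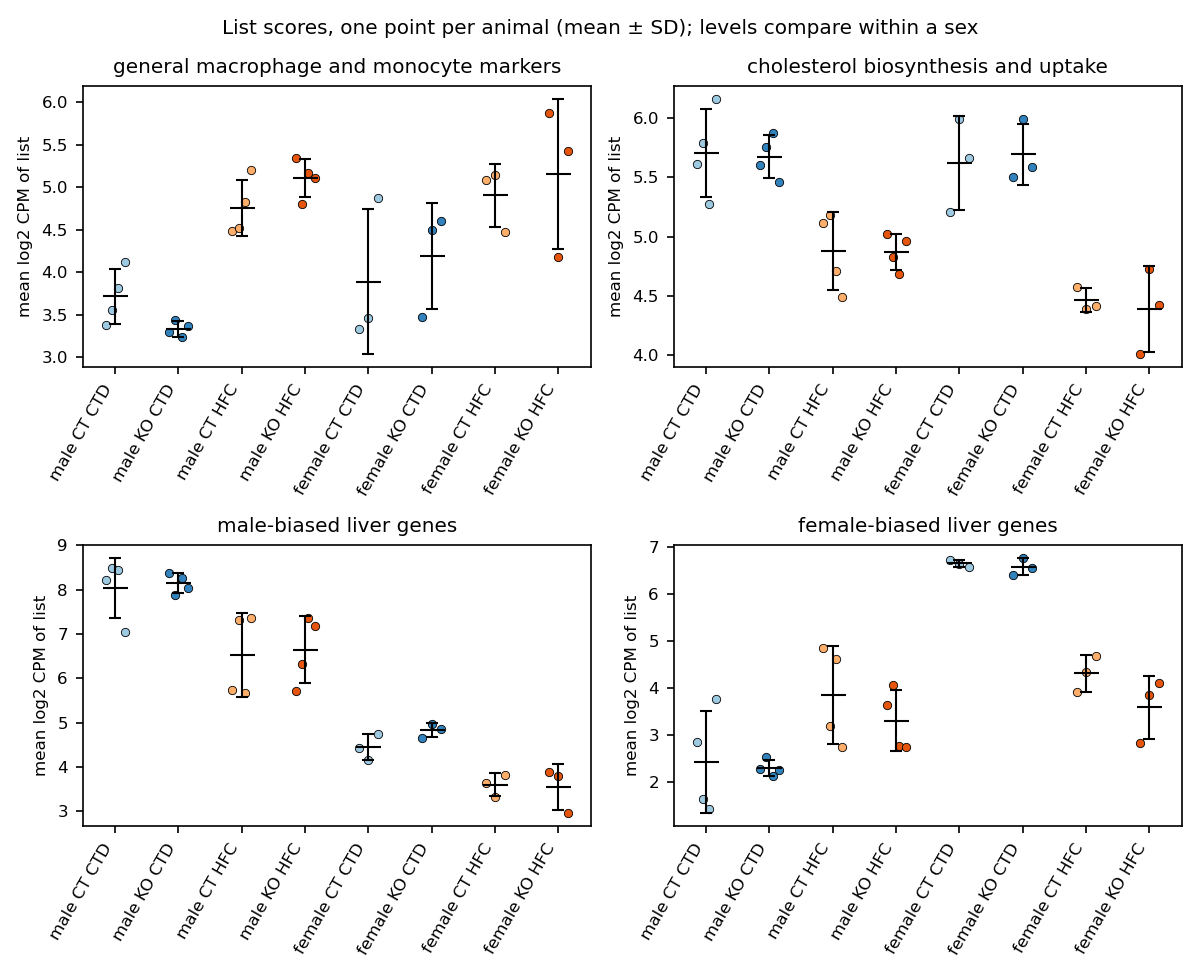
Mean log2 CPM of the members of 4 gene lists (vertical axes) in each group (horizontal axes), 1 point per animal, with mean and SD, where levels compare within a sex. Macrophage scores of males were 3.33 ± 0.09 in KO on CTD and 5.11 ± 0.22 in KO on HFC, against 3.72 ± 0.32 and 4.76 ± 0.33 in CT.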

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

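The tests of the 3 patterns weighed here were chosen after those patterns were seen, while the counts over other splits of the animals were planned.

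Among males, 160 sets of 4 libraries were examined for a library far from the other members of its group, and 12 were found by Dixon's test, where chance alone gives about 1 in 20. On CTD, the CT male 320 had 10.9% mitochondrial counts (others 12.1 to 12.3%), an endothelial activation score of 2.54 (others 2.19 to 2.23) and a bile acid score of 7.07 (others 7.38 to 7.39), all scores being mean log2 CPM. The KO male 311 on CTD had 22611870 counts (others up to 22403474) and a stress response score of 5.3 (others 5.46 to 5.49), and the KO male 298 a mesothelial score of 0.85 (others 1.95 to 2.17). On HFC, the CT male 416 had 11.5% mitochondrial counts (others 10.4 to 10.5%) and the CT male 418 a Myc target score of 4.4 (others 4.27 to 4.28). The KO male 540 on HFC had 22196484 counts (others from 22616573) and a fatty acid synthesis score of 7.13 (others 6.98 to 7). The KO male 414 on HFC had a matrix score of 4.46 (others 3.28 to 3.43) and a recruited macrophage score of 4.55 (others 3.19 to 3.42). A test of the sex difference in the diet effect picked out Car2 at log2 -1.30 (female minus male, adjusted p = 0.00127) and the female-biased list at -2.32 (camera adjusted p = 1.21e-21, adjusted p = 0.00788 with an estimated correlation). Of its 16 members 9 were tested in each sex, and for the other 7 the difference restates the female fall. Over the 9 the median was -1.45 (camera adjusted p = 0.000289, adjusted p = 0.905 with an estimated correlation).

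Macrophage markers lay higher in KO males on HFC and lower in KO males on CTD, with an interaction median of 0.75 log2. A single animal as the whole source is argued against, since the median stayed between 0.59 (without CT CTD 320) and 0.89 with any 1 male left out. A lower share of hepatocytes would raise endothelial markers as much, and the macrophage score exceeded the endothelial one by 0.58 in the interaction (exact two-sided permutation p = 0.122, 4900 regroupings). That p does not exclude it, because 4 animals a group leave a wide spread, so a shift in cell shares may still contribute. T and NK scores (0.60, unadjusted permutation p = 0.00571) and B and plasma cell scores (0.65, p = 0.0171) also had a positive interaction, and 0 lists passed after adjustment. Neutrophil scores did not, going from 0.08 on CTD to 1.57 on HFC in CT males and from -0.28 to 1.11 in KO males. Dendritic cell scores went from -0.07 to 0.65 in CT and from -0.16 to 0.75 in KO males. The lists were not tested against each other, so whether any difference by genotype is shared by all immune lists, and which cells it concerns, stays open.

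Female-biased liver genes lay lower on HFC in females, with a difference in list score of -2.66 log2 over both genotypes. A loss of hepatocytes as the whole source is argued against, since hepatocyte identity genes differed by -0.54 and the female-biased genes lay -2.12 below them (exact two-sided permutation p = 0.005 of 400 regroupings, the smallest they can give). Reads shared between Cyp3a copies are argued against as the whole source, since members outside that family differed by -1.55 (p = 0.005 by the same exact permutation), with 10 of 13 such members negative in CT and 11 in KO females. A change in the hormonal control of these genes may be a candidate explanation and was not tested. Diet and animal-number range cannot be told apart here.

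Male-biased liver genes lay lower in some HFC males than in others. The HFC males 414, 415, 416 and 418 had scores of 5.72, 6.33, 5.73 and 5.67, and the males 417, 539, 540 and 543 had 7.32, 7.36, 7.17 and 7.37. Genotype is argued against as the source, with a KO minus CT difference of 0.12 (exact two-sided permutation p = 0.857) and low and high animals in both genotypes. The animal-number series, 400s against 500s, differed by -1.14 (exact two-sided permutation p = 0.0536), which may reflect a cohort and cannot be told apart from individual variation with 3 animals in the 500s, male 417 being the exception. A low score was not confined to HFC, since CT male 320 on CTD had 7.04 where others of its group had 8.20 to 8.48. Female-biased scores were 3.62 to 4.84 in HFC males 414, 415, 416 and 418 and 2.74 to 3.18 in the other HFC males. In CT male 320 on CTD the female-biased score was 3.76. No biological explanation beyond genotype was tested.

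Other splits of the same animals were used to ask whether chance groupings of this size give as many called genes. For the diet in males 1 of 35 splits, the real one, reached the real count, with 2820 genes in CT (highest other 1) and 4102 in KO (highest other 0). This argues against chance, but 1 of 35 is the smallest share possible. The other splits mix the diets within a group, which widens the spread and lowers their counts. Where the real count is 0 every split reaches it, so these splits give no evidence on chance. That holds for KO against CT in males, 35 of 35 splits, with a highest other of 32 on HFC and 2 on CTD, and for the male interaction, 100 of 100 splits, with a highest other of 5. The split with 32 genes set 416 and 418 with 414 and 540, and a structure among the HFC males could lie behind it. In females 10 splits are too few for a share under 0.05, with real counts and highest others of 307 and 0 for the diet in CT, 1202 and 1 in KO, 0 and 0 for KO against CT on HFC and 0 and 9 on CTD.

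The same holds for the other contrasts with a real count of 0. All 100 splits reached it in the female interaction (highest other 374), in both sexes on HFC (246) and on CTD (41), and in the sex difference of the KO effect on HFC (221) and on CTD (58). Splits that call many genes where the real one calls 0 may point to a structure of the samples, whose source was not tested. For the sex difference of the diet effect 16 of 100 splits reached the real count of 1, with a highest other of 1233. The split with 1233 kept the females apart by diet and exchanged 3 of the 4 CTD males with HFC males, so it carries the diet effect itself. Splits of this kind give no evidence on chance for this contrast. Lists called by camera were as many in 2 of 35 splits for KO against CT in males on HFC (real 21, highest other 24) and in 24 of 35 on CTD (real 9, highest other 15). They were as many in 10 of 100 for the male interaction (real 17, highest other 22) and in 19 of 100 for both sexes on HFC (real 20, highest other 25). Chance cannot be excluded for these list counts, and for females on HFC the 10 splits are too few, with 4 reaching the real 14 (highest other 23). Without female KO HFC 412 camera called 6 lists in females on HFC and 10 in both sexes on HFC.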

How the results depend on the processing

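Library totals in place of TMM factors, permutation of list scores and lists limited to members tested in both sexes were chosen after the data were seen, and the other alternatives were planned. Unless a reason is given, the cause was not tested. With library totals the diet counts were 4537 in CT males, 1832 in CT females and 3738 in KO females, and the sex difference of the diet effect gave 3. Limma on the deposited CPM, which also has no TMM factors, gave 4614, 1798, 3485 and 24. The DESeq2 Wald test gave 919 for the diet in CT females, 1884 in KO females, 44 for its sex difference, 3 for KO against CT in males on HFC and 11 on CTD, 5 for the male interaction, 1 for females on CTD, 2 for both sexes on HFC and 1 on CTD, and 1 for the sex difference of KO on HFC. Groups fitted alone gave 804 for the diet in CT females and 435 in KO females. Genes of at least 1 CPM gave 4 for the sex difference of the diet effect. A term for the animal-number series within HFC left the counts of KO against CT on HFC unchanged in each sex and over both. Camera called 201 lists over all contrasts, and 1 with an estimated correlation, the female-biased list in the sex difference of the diet effect, which did not pass over members tested in both sexes (-1.45, adjusted p = 0.905).

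Leaving out 1 animal in turn gave 1753 to 3374 for the diet in CT males, 3065 to 4090 in KO males, 72 to 417 in CT females and 565 to 2671 in KO females. It gave 0 to 9 for KO against CT in females on HFC, 0 to 1 for the female interaction and for both sexes on each diet, 1 to 12 for the sex difference of the diet effect, and 0 for the other contrasts. With 1 animal left out, correlations of diet effects over all genes were 0.79 to 0.84 (CT and KO males), 0.71 to 0.79 (CT and KO females), 0.68 to 0.73 (CT males and females) and 0.66 to 0.76 (KO males and females). Over genes of at least 5 CPM with all animals they were 0.88, 0.86, 0.77 and 0.81. Lists whose direction by camera changed with 1 animal left out, given with their medians, were endothelial markers in males on HFC (0.01 without CT HFC 416, -0.22 without CT HFC 417), matrix genes in males on HFC (-0.04 without KO HFC 414, 0.39 without KO HFC 540) and in the male interaction (0.05 without KO HFC 414, 0.60 without CT CTD 313), acute phase genes in females on HFC (0.18 without CT HFC 510, -0.40 without CT HFC 512), and in both sexes on HFC cell cycle genes (-0.01 without female KO HFC 412, 0.56 without 413) and blood genes (-0.41 without female KO HFC 412, -0.06 without 413). With all animals the last 3 had medians of -0.17, 0.36 and -0.22 (camera adjusted p = 0.00282, 0.000692 and 0.0365, and 0.713, 0.526 and 0.526 with an estimated correlation), and the matrix interaction 0.38 (0.0296 and 0.708). Of single-gene results, 30 lost their call with library totals, 29 with limma, 29 without a filter, 44 with groups fitted alone, 1 with DESeq2 size factors and 0 with the DESeq2 test. With 1 animal left out 362 results lost their call and 2554 did not. The numbers not lost, here and for the diet below, include Myc, which was called in no contrast and so had no call to lose. For the diet the losses were 97 (119 not lost) in CT females and 139 (365) in KO females. In males they were 72 (872) in CT and 54 (1058) in KO. Of list results 252 lost their call with 1 animal left out and 1644 did not, while 200 lost it with an estimated correlation, 13 at 1 CPM and 2 with DESeq2 size factors. At this depth and group size the simulation recovered 4% of genes changed by log2 0.5 in females and 48% in males, so KO effects of that size or below would mostly be missed. Its changed genes excluded those with few counts and its groups held no animal standing apart, so recovery in the deposited data may be lower.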

Other observations

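The test of the diet axis at the end was planned before its result was seen, and the gene groups described before it carry the tests of the comparisons they come from.

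Further groups moved with diet in males. Of 12 neutrophil markers 7 rose in CT males (10 adjusted over the list alone; camera adjusted p = 5.57e-05, adjusted p = 0.192 with an estimated correlation), with S100a9 at log2 1.83 (SE 0.37). Icam1, an adhesion molecule for leukocytes, rose from 10.7 ± 1.87 to 23.8 ± 3.47 CPM in CT males and from 11.7 ± 0.913 to 30.7 ± 3.73 CPM in KO males (SD, n = 4), and Vcam1 rose by 1.19 (SE 0.28) in KO males. Of 12 B and plasma cell markers 9 rose in KO males (camera adjusted p = 3.16e-05, adjusted p = 0.0864 with an estimated correlation). Of 16 glucose metabolism genes 8 fell in KO males (9 adjusted over the list alone; camera adjusted p = 2.58e-05, adjusted p = 0.0864 with an estimated correlation), with Pck1, a gluconeogenic enzyme, at -1.05 (SE 0.22). Of 5 mesothelial genes 4 fell in KO males, with Upk1b at -1.99 (SE 0.48) (camera adjusted p = 0.00988, adjusted p = 0.334 with an estimated correlation). Of 48 Myc targets 2 rose and 12 fell in KO males, with a median of -0.08 that was 0.20 on library totals (camera adjusted p = 0.0386, adjusted p = 0.454 with an estimated correlation). That call was lost without KO CTD 311 (-0.05, adjusted p = 0.073) or KO HFC 539 (-0.06, adjusted p = 0.15) and with genes of at least 1 CPM alone (-0.06, adjusted p = 0.081).

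In females, the diet raised the stress hormone gene Fgf21 in KO livers (log2 2.56, SE 0.40) and Cyp2c55 (3.54, SE 0.51), and lowered the glucose-releasing enzyme gene G6pc (-1.78, SE 0.32). Of 12 sterol efflux and LXR targets 4 rose in CT and 4 in KO females (5 in each adjusted over the list alone), with camera adjusted p = 0.00505 and 0.00192, and adjusted p = 0.365 and 0.278 with an estimated correlation.

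A hypothesis was that KO livers on HFC lie further along the diet response than CT livers on HFC. Each liver was placed on an axis defined by the diet effect of the other sex, with the mean of CT on CTD at 0 and that of CT on HFC at 1. Male KO livers on HFC lay at 1.07 ± 0.21, where CT livers had an SD of 0.19 (n = 4), and female KO livers at 1.22 ± 0.51, where CT livers had an SD of 0.25 (n = 3). Over both sexes the KO minus CT difference was 0.15 (two-sided permutation p = 0.404, 1400 regroupings), and it was 0.06 on CTD (permutation p = 0.559). Without female KO HFC 413, which lay at 0.64 where the other female KO livers lay at 1.61 and 1.41, the HFC difference was 0.29 (permutation p = 0.0743). Without female KO HFC 412 it was 0.05 (permutation p = 0.774). Female CT HFC 512 also lay low, at 0.71 where the other female CT livers on HFC lay at 1.16 and 1.13. Without it the HFC difference was 0.07 (permutation p = 0.734). These values come from leaving out each HFC animal in turn, which was added after the data were seen. A p above the threshold with 4 and 3 animals a group does not exclude the hypothesis, since the spread within groups is larger than the difference, and a small shift may remain undetected.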
